A study of Homo sapiens with 6 samples.

How the data were processed

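Poly(A)-selected RNA from 6 A549 samples was sequenced as paired reads of 150 nt, per the labels' protocols, 3 samples with miR-19a and 3 with the control miR-NC at 25 nM. Reads were demultiplexed with bcl2fastq 2.17.1.14, per the submitters' processing notes. The aligner, counting tool, annotation, strand setting and genome build are not given in the sources used here. The deposited table gives, for each of 57905 gene identifiers, a whole-number count and an FPKM value per sample, with column names that match the sample titles. The authors' FPKM values, named so per the file headers, were rounded to 2 decimals and are scaled for gene length and library total, whereas the deposited counts are not normalized. No row without a gene was in the table. Symbols came from a table of gene names for 39538 identifiers and from GENCODE v29 for 12800, and 5567 had no symbol.

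The tests had been planned on FPKM, before the data were examined, and the table turned out to hold counts as well. The main test was therefore edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, two-sided, with TMM factors and Benjamini-Hochberg adjustment, and the planned limma test (limma 3.58.1) on log2(FPKM + 1) was kept as an alternative. Genes with a mean FPKM of at least 1 over the 6 libraries were tested (12452 genes). The common biological coefficient of variation was 0.0352. A standard error was taken as the absolute log2 fold change over the square root of F. CPM are TMM-scaled, and means ± SD are over 3 libraries. Total counts lay between 15699037 and 17957932 per library, and intervals on shares cover counting error only.

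3′ UTRs were cut from GENCODE v29 transcripts on GRCh38 for 18737 protein-coding genes, using the transcript with the longest coding sequence, and 10428 tested genes had one. Each gene was put in its strongest miR-19a class: 8mer TTTGCACA, 7mer-m8 TTTGCAC, 7mer-A1 TTGCACA or 6mer TTGCAC. Classes, 18 other microRNA families and gene lists were tested with camera (correlation preset at 0.01), classes against the other tested genes with a UTR, families against the other genes among those without a miR-19a site of 7 nt or more, and lists against all other tested genes, and again with an estimated correlation. The run with the preset correlation took z values from the edgeR p-values, whereas the run with an estimated correlation was camera on the counts. These runs therefore differ in the gene statistic as well as in the correlation. Coding sites were tested among genes with no miR-19a site in the 3′ UTR. fry was run beside camera for the lists and the classes of 3′ UTR sites, not for the families, and asks whether the genes of a set move one way on balance. Medians were set beside 10000 random gene sets matched on 10 bins of UTR length and 5 of expression. These draws treat genes as independent, so they take no account of correlation between genes. The statistic of each 7-mer is a rank-sum z of fold change after a smooth trend on log UTR length and UTR GC content was removed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

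The 31 gene and marker lists were fixed before the data were examined, and 27 had enough expressed members to test. 21 list entries matched no identifier and were not used, 12 of them older names of histone genes. Genes named in the text are the 10 with the largest rise and the 10 with the largest fall in log2(FPKM + 1), among genes past the threshold with separated groups and a symbol, then BCL2L11, SOCS1, ZMYND11, MYC, CCND1 and MIR17HG, at most 2 rising and 2 falling members of each list with the smallest adjusted p, and the 5 largest falls of each site class. MT1A was passed over as a member of a near-identical family, and SNORA66 and MIR4737, small RNAs that poly(A) selection does not capture reliably, by a choice made after the data were seen. Some genes that this rule takes in are not reported here. Coordinates come from the match to GRCh38, not from the deposited table.

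On simulated counts for 12452 genes of the miR-19a against miR-NC comparison, the count test recovered 34, 43, 46 and 50 of 50 genes changed by 1.25, 1.5, 2 and 4 fold, with 4 false calls among 12252 unchanged genes. Every simulated gene had the common dispersion and most were unchanged. In the data dispersion varies by gene and 6023 genes passed, so these counts do not measure performance there. The 7-mer scan ranked a planted 7-mer first among shuffled fold changes. Alternatives fixed in advance were other pseudocounts, gene filters, TPM, median-of-ratios factors, quantile normalization, no intensity trend, a replicate block, a fold minimum, each library left out in turn, the longest 3′ UTR, no trend correction, sites kept, estimated correlation and fry. DESeq2 1.42.0, library totals alone and edgeR's filterByExpr were added after the data were seen. The pseudocount, TPM, quantile and trend alternatives were run with limma, since the count test takes no pseudocount.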

Results

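RNA from 6 samples of A549, an established human lung adenocarcinoma cell line, was sequenced after poly(A) selection. In 3 samples the cells had received miR-19a at 25 nM, and in 3 samples a negative control microRNA (miR-NC) at the same concentration, with harvest given as 24 h. miR-19a is a microRNA of the MIR17HG cluster that lowers messenger RNAs pairing with its seed. Total counts over genes were 16652353, 16127606 and 15699037 for miR-NC replicates 1 to 3 and 16323470, 17196591 and 17957932 for miR-19a replicates 1 to 3. Within each group every pair of libraries differed by more than sampling noise, with a chi-square per gene between 1.60 and 4.22, and pairs taken across the groups lay between 27.3 and 30.9. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

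The single comparison of the design asks which transcripts differ between cells given miR-19a and cells given the control. The largest rises included IL32, a proinflammatory cytokine, CCL20, a chemokine, IL11, an interleukin of the IL6 family, and the fibrinogen chains FGG and FGA. The largest falls included GET3, an ATPase that delivers tail-anchored proteins to the endoplasmic reticulum, the ubiquitin ligase RNF11, and ZMYND11, a chromatin reader. Of 12452 genes tested with edgeR, 6023 passed an adjusted p of 0.05, with 3095 higher and 2928 lower in miR-19a. Most of these changes were small, and 242 genes (129 higher and 113 lower) also differed by at least 1 on the log2 scale. The 3 libraries of one group lay wholly above those of the other for 6720 genes (54.0%), where chance gives 10%.

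IL32 (ENSG00000008517) rose from 16.6 ± 0.919 to 93.6 ± 7.09 normalised counts (CPM; mean ± SD, n = 3 per group), a log2 fold change of 2.49 (SE 0.065, adjusted p = 2.0e-42). FGG (ENSG00000171557) rose by 2.47 (SE 0.088, adjusted p = 4.6e-35), from 7.47 ± 0.308 to 41.5 ± 3.58 CPM, and FGA by 1.67 (SE 0.067). CCL20 (ENSG00000115009), which has a 7mer-A1 site for miR-19a in the 3′ UTR, rose by 2.40 (SE 0.12) from a low level of 4.51 ± 1.37 CPM. IL11 (ENSG00000095752) went from 36.9 ± 1.07 to 154.7 ± 2.5 CPM, a rise of 2.07 (SE 0.050, adjusted p = 4.4e-44). SLC2A3, a glucose transporter, rose by 2.02 (SE 0.053), and GXYLT1, a xylosyltransferase with a 7mer-m8 site, by 1.82 (SE 0.055). GPAT3, an acyltransferase of triglyceride synthesis, rose by 1.67 (SE 0.049), the secreted hormone STC1 by 1.62 (SE 0.046) and the neuropeptide precursor NTS by 1.59 (SE 0.071).

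Among the 10 genes with the largest fall, 6 carried an 8mer site for miR-19a in the 3′ UTR. These were GET3, RNF11, ZMYND11, IMPDH1, SNX17 and MRPL17. GET3 (ENSG00000198356) fell from 70.0 ± 3.15 to 20.7 ± 1.23 CPM, a log2 fold change of -1.76 (SE 0.064, adjusted p = 1.1e-34). RNF11 (ENSG00000123091) had a log2 fold change of -1.71 (SE 0.076) and ZMYND11 (ENSG00000015171) one of -1.62 (SE 0.054). IMPDH1, a rate-limiting enzyme of guanine nucleotide synthesis, had a change of -1.49 (SE 0.059), the sorting nexin SNX17 of -1.36 (SE 0.044) and MRPL17, a mitochondrial ribosomal protein, of -1.31 (SE 0.058). NUPR1, a stress-induced chromatin protein, at -2.14 (SE 0.18), the kinase STK26 at -1.82 (SE 0.095) and ALDH3A1, an aldehyde dehydrogenase, at -1.28 (SE 0.037) had no site in the 3′ UTR used. GACAT2, at -2.68 (SE 0.17), is annotated as antisense, and since strand in the counting is not given in the sources used here, its reads cannot be told from those of genes on the other strand.

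**Figure D1:**
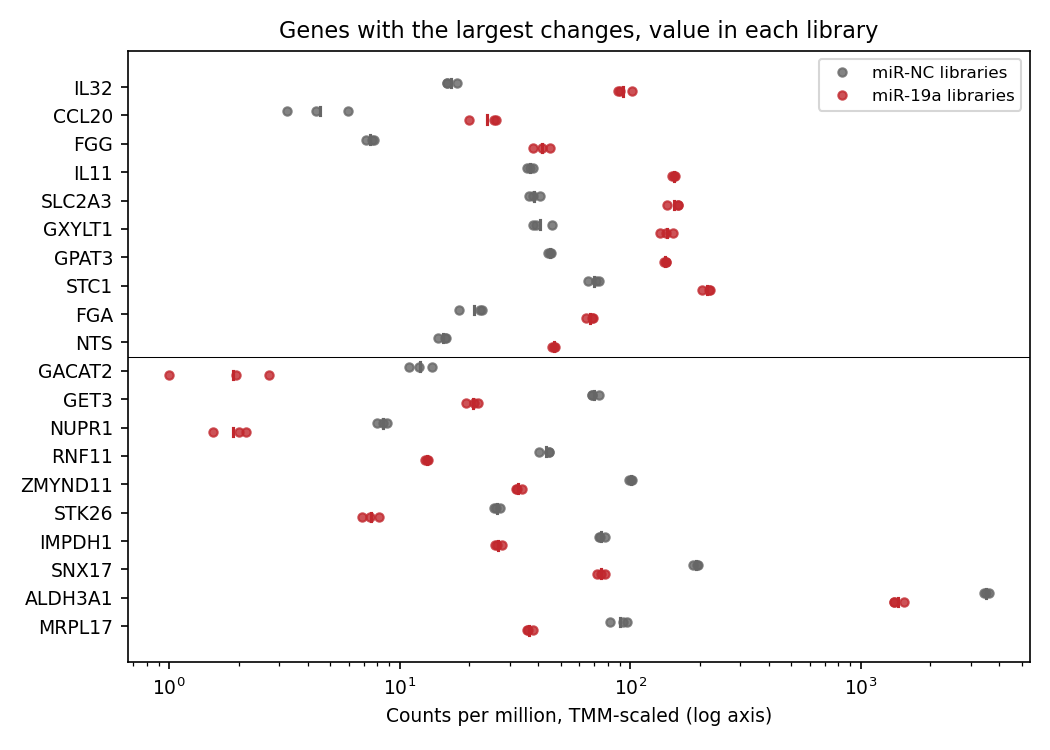
TMM-scaled counts (CPM, log axis) in each of the 6 libraries for the 10 genes with the largest rise (above the line) and the 10 with the largest fall (below it). Points are libraries, grey for miR-NC and red for miR-19a, and short vertical bars are group means of 3 libraries. The groups do not overlap for any of these genes, and IL32 stood at 16.6 in miR-NC and 93.6 in miR-19a on average.

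Transcripts with an 8mer or 7mer-m8 seed site for miR-19a in the 3′ UTR were lower in the miR-19a samples, and the medians of the classes followed the strength of the site. The 631 genes with an 8mer site (TTTGCACA) had a median log2 fold change of -0.15, with 306 lower and 98 higher. The 774 genes whose strongest site was a 7mer-m8 had a median of -0.06 (286 lower, 185 higher) and the 548 with a 7mer-A1 one of -0.03 (177 lower, 146 higher). The 968 genes with only a 6mer had a median of 0.01 (231 lower, 282 higher), and the 7507 genes with no site one of 0.03 (1605 lower, 2215 higher). Genes with several 8mer sites (n = 44) had a median of -0.24, against -0.15 for the 587 with one; this difference was not tested. Random gene sets matched on 3′ UTR length and expression gave a median of 0.03 for the 8mer class. For each of the 8mer, 7mer-m8 and 7mer-A1 classes 0 of 10000 sets were as low as observed, against 1783 of 10000 for the 6mer class. The draws treat genes as independent. With camera the 8mer class stood below other genes at adjusted p = 8.9e-10 (adjusted p = 0.0711 with an estimated correlation), the 7mer-m8 class at adjusted p = 0.031 (adjusted p = 0.409 with an estimated correlation), and the 7mer-A1 and 6mer classes did not pass at 0.168 and 0.625. The 7mer-m8 call also ended with DESeq2 (adjusted p = 0.0583), with either wider gene filter (0.0569 and 0.135), without miR-19a replicate 3 (0.0512) and without miR-NC replicate 2 (0.0990).

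Of 2605 lower genes with an annotated 3′ UTR, 769 (29.5%, exact 95% interval 27.8 to 31.3) carried a 7mer or 8mer site. The share was 14.7% (of 2926 genes, interval 13.4 to 16) among higher genes and 15.4% among genes that did not pass. Lower against higher genes gave an odds ratio of 2.44 (two-sided Fisher's exact test across genes, which are not independent replicates, p = 5.0e-41). Among genes lower by at least 1 on the log2 scale, 40 of 73 (54.8%) had such a site, against 15 of 117 (12.8%) among those higher by as much. The other 1836 lower genes (70.5%) had none.

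Positions of sites are given on GRCh38 with GENCODE v29 transcripts, all in the 3′ UTR and within a single exon. ZMYND11, on chromosome 10, carried 8mers at 252604 to 252611 and 253192 to 253199, a 7mer-m8 at 252568 to 252574 and a 7mer-A1 at 254317 to 254323. Its level went from 100.8 ± 1.45 to 32.7 ± 1.07 CPM (adjusted p = 1.3e-36). RNF11 had 8mers on chromosome 1 at 51271809 to 51271816 and 51272472 to 51272479, and GET3 had one on chromosome 19 at 12748175 to 12748182. IMPDH1, on the minus strand of chromosome 7, had an 8mer at 128392349 to 128392356 and a 7mer-m8 at 128392909 to 128392915. TRAK2, an adaptor of mitochondrial transport with an 8mer on chromosome 2 at 201379500 to 201379507, had a log2 fold change of -1.47 (SE 0.074). In the 7mer-m8 class large falls included those of E2F2, a cell cycle transcription factor, at -1.51 (SE 0.16), UNC93B1, a chaperone of Toll-like receptors, at -1.36 (SE 0.066), FGFBP3 at -1.32 (SE 0.17), and ATP6V0E1, a subunit of the vacuolar proton pump, at -1.23 (SE 0.047). In the 7mer-A1 class they were SLC49A4 at -1.51 (SE 0.10), ABHD14B at -1.37 (SE 0.084), RTL8B at -1.13 (SE 0.14), TMEM64 at -1.11 (SE 0.070) and RAB26 at -1.05 (SE 0.21). RTL8B has close paralogs whose reads may be shared.

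**Figure D2:**
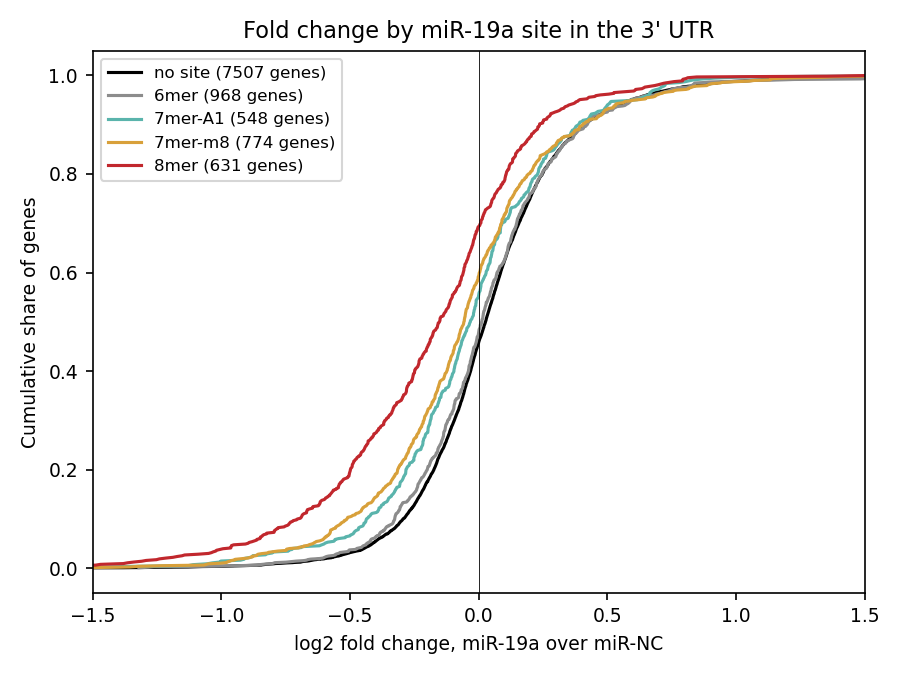
Cumulative share of genes (vertical axis) against log2 fold change of miR-19a over miR-NC (horizontal axis, drawn from -1.5 to 1.5) by the strongest miR-19a site in the 3′ UTR. Each line is a class of genes, and the 8mer line lies farthest to the left, with 69.3% of its 631 genes below 0.

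A scan of all 7-mers in 3′ UTRs, after a trend on UTR length and GC content was removed, named no sequence in advance. The lowest rank-sum statistics belonged to the miR-19a seed matches TTTGCAC (-18.0, 1405 genes) and TTGCACA (-17.0, 1291 genes). The next, TGCACAT, which overlaps the same match, stood at -9.91. On the opposite side TGGTGCT, the seed match of miR-29, ranked first at 7.0, and CTACCTC, that of let-7, stood at 4.42. A single shuffle of fold changes across genes, which takes no account of correlation between genes, reached -3.70 and 3.53.

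**Figure D3:**
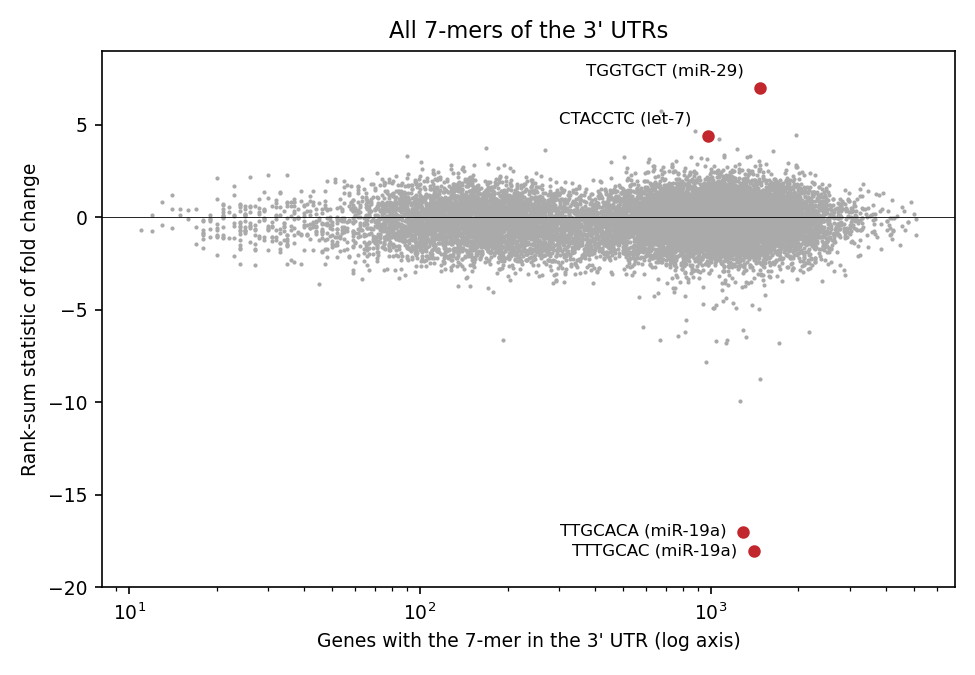
Rank-sum statistic of log2 fold change for every 7-mer (vertical axis, no unit) against the number of genes carrying it in the 3′ UTR (horizontal axis, log scale). Each grey point is a 7-mer, and red points mark seed matches, with TTTGCAC at -18.0 and TGGTGCT at 7.0.

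Genes with sites for other microRNAs, and no miR-19a site of 7 nt or more, had medians above 0 for each of the 18 families examined. miR-29 sites went with the highest median, 0.11 over 1003 genes (431 higher, 169 lower), followed by let-7 (0.11, 655 genes) and miR-92/25 (0.11, 682 genes). Camera called 7 families at an adjusted p under 0.05, with miR-29 at 0.0054, and no family with an estimated correlation (adjusted p = 0.224 for miR-29 and let-7 and 0.455 for the other 5 called families). The number of families called was 4 without miR-19a replicate 1, 1 without miR-19a replicate 2, 11 without miR-19a replicate 3, 1 without miR-NC replicate 1 and 2 without miR-NC replicate 3. It was 1 with each of DESeq2, filterByExpr, limma on TPM and no filter. Gene sets matched on UTR length and expression also had medians above 0, of 0.05 to 0.06. Against matched sets miR-29 lay higher by 0.0580, let-7 by 0.0563, miR-92/25 by 0.0476, miR-21 by 0.0420, miR-27 by 0.0378, miR-30 by 0.0224 and miR-200b by 0.0218, all at an adjusted p between 0.0012 and 0.0278. miR-23, called by camera (adjusted p = 0.0446), did not differ from matched sets (0.0103, adjusted p = 0.348), and miR-200b was not called by camera (adjusted p = 0.0972). With genes carrying a miR-19a site kept no family was called (adjusted p = 0.123 for miR-29). The matched p of miR-29, let-7 and miR-92/25, 0.0002, is the smallest the draws can give. All matched p treat genes as independent replicates, which they are not, and take no account of correlation within a family. Sites for miR-19a-5p, the other strand of the duplex, did not differ from matched sets (-0.0014, adjusted p = 0.908).

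Of the 27 tested members of the list of known miR-19 targets, 17 fell and 4 rose, and adjusted over the list alone the counts were 17 and 4. The list had a median log2 fold change of -0.21 (camera adjusted p = 0.0045; adjusted p = 0.245 with an estimated correlation). ZMYND11 fell most, followed by PRKAA1, a catalytic subunit of AMP-activated kinase, at -1.13 (SE 0.055), which had no site in the 3′ UTR used. CCND1, cyclin D1, which has an 8mer, fell by 0.16 (SE 0.037). BCL2L11, a proapoptotic BCL2 family member with a 7mer-m8, did not pass at -0.09 (SE 0.087, adjusted p = 0.389). Against the direction of the list, the small GTPase RHOB rose by 0.79 (SE 0.039) with an 8mer in its 3′ UTR, and the acetyltransferase KAT2B by 0.78 (SE 0.072) with a 7mer-A1. SOCS1 (0.994 and 0.889 CPM in miR-NC and miR-19a) and the cluster transcript MIR17HG (3.14 and 3.13 CPM) lay under the expression filter. With a stricter filter of mean FPKM 5 the list's call ended (median -0.13, adjusted p = 0.231).

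Enzymes of cholesterol synthesis rose together. Of 23 tested members 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 7.6e-19; adjusted p = 0.0473 with an estimated correlation). HMGCS1, HMG-CoA synthase, rose by 1.33 (SE 0.042), from 156.5 ± 8.82 to 394.6 ± 19.6 CPM, although it carries a 7mer-m8. MSMO1, a sterol monooxygenase that also has a 7mer-m8, fell by 0.34 (SE 0.064). In fatty acid synthesis 8 of 10 members rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.0025; adjusted p = 0.351 with an estimated correlation). SCD, stearoyl-CoA desaturase, which has a 7mer-m8, rose by 0.83 (SE 0.039) and FADS2, a fatty acid desaturase, by 0.54 (SE 0.040). FASN, fatty acid synthase, fell by 0.34 (SE 0.041).

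Inflammatory and early response genes were also higher. Of 20 NF-kB targets 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.27 (adjusted p = 2.0e-06; adjusted p = 0.0473 with an estimated correlation). Next to CCL20, the neutrophil chemokine CXCL8 rose by 1.54 (SE 0.055), from 39.8 ± 2.69 to 115.9 ± 7.52 CPM, and the adaptor TRAF1 fell by 0.51 (SE 0.068). Of 19 immediate early genes 13 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.59 (adjusted p = 9.2e-06; adjusted p = 0.0473 with an estimated correlation). The nuclear receptor NR4A1 rose by 1.04 (SE 0.063) and the AP-1 subunit JUNB by 0.72 (SE 0.043), whereas FOSL1, another AP-1 subunit and a carrier of a 7mer-m8, fell by 0.82 (SE 0.052) and MYC by 0.20 (SE 0.042). Of 23 interferon response genes 5 rose and 10 fell (5 and 11 adjusted over the list alone), with a median of -0.01 and no call for the list (adjusted p = 0.589). RSAD2, an antiviral enzyme, rose by 1.05 (SE 0.084), and the RNA sensor RIGI fell by 0.40 (SE 0.051).

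In the unfolded protein and ATF4 list 15 of 21 members rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.33 (adjusted p = 2.0e-06; adjusted p = 0.0914 with an estimated correlation). TRIB3, a pseudokinase, rose by 0.78 (SE 0.043) and DDIT4, an inhibitor of mTORC1, by 0.68 (SE 0.039). DDIT3, the factor CHOP, fell by 0.28 (SE 0.10), a call that ended without miR-19a replicate 2 (-0.22, adjusted p = 0.125), without miR-NC replicate 1 (-0.26, adjusted p = 0.0598) and without miR-NC replicate 3 (-0.18, adjusted p = 0.184), as well as with DESeq2 (adjusted p = 0.0655) and limma. Of 18 apoptosis regulators 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.0025; adjusted p = 0.245 with an estimated correlation). Members of opposite function rose, with the survival factor MCL1 at 0.43 (SE 0.038) and the proapoptotic BBC3 at 0.56 (SE 0.057). BCL2L1, which encodes BCL-xL, fell by 0.21 (SE 0.037). Of 10 FOXO targets 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0044, and 0.245 with an estimated correlation). Among those that rose were BBC3 and the transcription factor KLF6, which has a 7mer-A1, at 0.68 (SE 0.045). The p53 targets (11 of 22 rose and 6 fell, 11 and 7 adjusted over the list alone) were not called at adjusted p = 0.111, with CCNG1 at 0.75 (SE 0.044) and GDF15 at -0.82 (SE 0.045).

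Genes of mitosis were lower. Of 20 G2/M genes 17 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.28 (adjusted p = 2.0e-06; adjusted p = 0.396 with an estimated correlation). The mitotic kinase PLK1 fell by 0.64 (SE 0.048), from 121.3 ± 4.27 to 77.8 ± 5.19 CPM, and CDC20, an activator of the anaphase-promoting complex, by 0.64 (SE 0.050). CDK1 did not pass at 0.10 (SE 0.056, adjusted p = 0.134). Of 21 S phase genes 10 fell and 4 rose (10 and 4 adjusted over the list alone), without a call for the list (median -0.13, adjusted p = 0.106). The helicase subunits MCM6 and MCM2 each fell by 0.36 (SE 0.050 and 0.055), and CCNE1, cyclin E, rose by 0.30 (SE 0.061). Of 26 genes known to be raised by MYC 16 fell and 2 rose (17 and 3 adjusted over the list alone), with a median of -0.13 (adjusted p = 0.0070; adjusted p = 0.490 with an estimated correlation). FBL, a nucleolar methyltransferase, fell by 0.48 (SE 0.039), and TFRC, the transferrin receptor, rose by 0.39 (SE 0.037).

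Epithelial and mesenchymal marker lists were both higher on balance. Of 12 epithelial markers 8 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.26, adjusted p = 0.0069; adjusted p = 0.245 with an estimated correlation), with the tight junction protein CLDN1 at 0.90 (SE 0.038) and keratin KRT7 at -0.28 (SE 0.036). Of 14 mesenchymal markers 8 rose and 3 fell (8 and 4 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.042, and 0.245 with an estimated correlation). The integrin ITGA5 stood at 1.06 (SE 0.042), the transcription factor SNAI1 at 0.92 (SE 0.097) and the matrix protein TGFBI, with a 7mer-A1, at -0.30 (SE 0.035). The mesenchymal call ended without miR-19a replicate 3 (adjusted p = 0.0565), without miR-NC replicate 3 (0.0552), with filterByExpr (0.1), at mean FPKM 5 (0.307) and on the FPKM scale. Of the 15 lung fibroblast markers 5 were expressed above the filter, of which 3 rose and 0 fell (3 and 1 adjusted over the list alone; adjusted p = 0.0063; adjusted p = 0.245 with an estimated correlation). COL1A1 rose by 1.52 (SE 0.095), from 8.93 ± 1.02 to 25.6 ± 1.78 CPM, and COL5A1 by 1.22 (SE 0.043), while TWIST2 (-0.33, SE 0.16) and ACTA2 (-0.15, SE 0.090) did not pass, and this call was also lost on the FPKM scale (adjusted p between 0.0971 and 0.142). TGF-beta response genes went both ways, with 8 of 22 higher and 9 lower (8 and 9 adjusted over the list alone; adjusted p = 0.589), from the basement membrane collagen COL4A1 at 1.17 (SE 0.041) and the receptor TGFBR1 at 1.16 (SE 0.054) to the membrane protein PMEPA1, with an 8mer, at -0.58 (SE 0.041). YAP targets were not called (5 of 15 higher, 4 lower, 5 and 4 adjusted over the list alone; adjusted p = 0.370), with LATS2 at 0.78 (SE 0.061) and PTPN14, a carrier of a 7mer-m8, at -0.45 (SE 0.060). Of other lung cell markers, the mucin MUC5AC fell from 30.1 ± 1.59 to 11.5 ± 1.17 CPM (-1.38, SE 0.086) and the transcription factor ETV5, which has an 8mer, by 0.71 (SE 0.073), and the lipid transporter ABCA3 did not pass at 0.12 (SE 0.063). The only leukocyte marker above the filter, CD14, stood near the floor at 1.92 ± 0.456 and 2.93 ± 0.356 CPM (0.61, SE 0.23, adjusted p = 0.025). The CD14 call ended with DESeq2 (adjusted p = 0.077) and without miR-19a replicate 3 (0.119), miR-NC replicate 1 (0.0553) or miR-NC replicate 3 (0.130). None of the 6 endothelial markers matched to an identifier lay above the filter, and PECAM1 was not matched.

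NRF2 targets split. Of 23 members 11 fell and 6 rose (11 and 6 adjusted over the list alone), with a median of -0.03 (adjusted p = 0.0058; adjusted p = 0.245 with an estimated correlation). ALDH3A1 went from 3514 ± 82.9 to 1446 ± 78.8 CPM, and the transporter ABCC3, with an 8mer, fell by 0.96 (SE 0.040). TXNRD1, thioredoxin reductase, rose by 0.33 (SE 0.035) and SRXN1, sulfiredoxin, which has a 7mer-m8, by 0.49 (SE 0.063). The call ended on the FPKM scale (adjusted p between 0.0736 and 0.105). Of 13 mitochondrially encoded genes 9 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.14, adjusted p = 0.0086; adjusted p = 0.654 with an estimated correlation), with MT-CO2 at -0.25 (SE 0.040). The call was also lost with DESeq2 (adjusted p = 0.081), with fry (adjusted p = 0.117) and without miR-NC replicate 2 (median -0.09, adjusted p = 0.0668). After quantile normalization the median was 0 (adjusted p = 0.623). Mitochondrial genes took 7.16%, 7.66% and 6.77% of counts in miR-NC replicates 1 to 3 and 6.43%, 6.41% and 6.25% in miR-19a replicates 1 to 3. Nuclear genes of the respiratory chain (4 of 30 higher, 8 lower, 4 and 8 adjusted over the list alone) and ribosomal proteins (2 of 40 higher, 3 lower, 1 and 2 adjusted over the list alone) were not called at adjusted p = 0.873 and 0.995.

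The glycolysis and hypoxia list was not called (6 of 24 higher, 9 lower, 6 and 9 adjusted over the list alone, camera adjusted p = 0.355). Even so the glycolytic kinase PGK1, with a 7mer-A1, fell by 0.48 (SE 0.036) and PFKFB4 rose by 0.79 (SE 0.093). Heat shock proteins (3 of 12 higher, 4 lower, 4 and 4 adjusted over the list alone; adjusted p = 0.701) were led by HSPB1 at 0.60 (SE 0.037). Autophagy and lysosome genes (10 of 27 higher, 6 lower, 10 and 6 adjusted over the list alone; adjusted p = 0.401) held NEU1, a lysosomal sialidase, at 0.67 (SE 0.061) and ATG16L1, an autophagy protein with a 7mer-m8, at -0.56 (SE 0.051). Replication-dependent histone genes were not called (1 of 6 higher, 2 lower, 1 and 2 adjusted over the list alone, camera adjusted p = 0.589). They held H2AC6 at -0.54 (SE 0.075), whose reads may be shared with near-identical copies. Only their poly(A)-selected RNA was measured, which may not stand for the whole of their messenger RNA. In the small RNA machinery 2 of 10 members rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.995). The Argonaute gene AGO4, with a 7mer-m8, stood at 0.69 (SE 0.10) and XPO5, the precursor microRNA exporter, at -0.21 (SE 0.052). Median and mean had opposite signs for the glycolysis, heat shock, respiratory chain and small RNA lists, and the test pointed down for ribosomal proteins although median and mean lay above 0. Of the 15 lists called with the preset correlation, those of cholesterol synthesis, NF-kB targets and immediate early genes, 3 in all, held with an estimated correlation. The estimated run also used another gene statistic, so a lost call does not measure correlation alone. For immediate early genes the camera p went from 1.7e-06 to 0.0053 at an estimated correlation of -0.0063, below the preset 0.01.

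**Figure D4:**
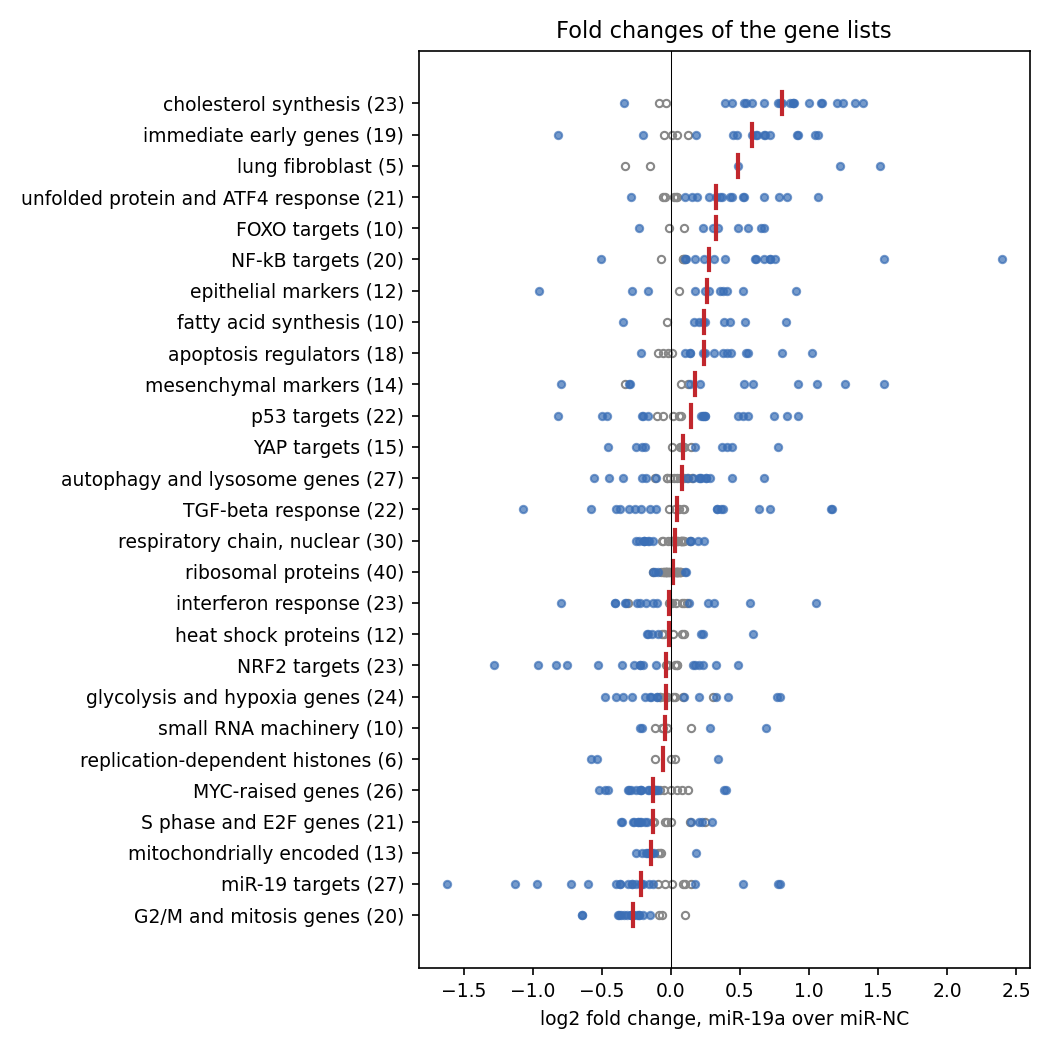
Log2 fold change of miR-19a over miR-NC (horizontal axis) for the tested members of each gene list (vertical axis, number of members in brackets). Points are genes, filled where the adjusted p is under 0.05 and open otherwise, and red bars are list medians, from 0.81 for cholesterol synthesis to -0.28 for G2/M genes.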

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

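The test of the split was fixed before the data were examined, and the genes under the expression filter were chosen after their values were seen.

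Genes under the expression filter stand outside the comparison of the report. When no filter was used, 704 of 16482 such genes passed the edgeR threshold (360 higher and 344 lower in miR-19a). The 3 with the smallest adjusted p are named here. MYOCD, a cofactor of smooth muscle transcription, rose by 2.02 (SE 0.16), with 34, 56 and 26 counts in miR-NC and 159, 170 and 165 in miR-19a. NR4A3, an orphan nuclear receptor, rose by 2.07 (SE 0.17), with 40, 32 and 23 counts against 123, 135 and 159. ACVR2B, an activin receptor, rose by 1.17 (SE 0.099), with 151, 167 and 132 counts against 362, 319 and 375.

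Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 6023, and the highest of the others gave 0. With 10 splits a share under 0.05 is out of reach.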

How the results depend on the processing

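DESeq2, filterByExpr and library totals alone were chosen after the data were seen, and so were edgeR as the main test and the use of limma on log2(FPKM + 1), until then the planned main test, as an alternative. No result of the text changed direction past its threshold under any alternative run. Over settings without a fold minimum, 4070 (mean FPKM of at least 5, with 7251 genes tested) to 6620 (filterByExpr) genes passed, 5186 with DESeq2, 5325 to 5784 with a library left out, and a fold minimum of 1 left 242 (129 higher, 113 lower). Of 139 named genes, 2554 of 2618 values kept their side of the threshold, 58 fell short and 6 passed anew. Values that passed in neither setting count as kept even where their sign differed.

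The replicate numbers do not pair the libraries (correlations 0.0085, 0.0005 and -0.031, with 1 library closest to its own number). With a replicate block 5986 genes passed (3083 higher, 2903 lower), the 7mer-m8 median was -0.0573 (adjusted p = 0.0664) and 4 microRNA families were called in place of 7.

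The 8mer class missed the threshold with an estimated correlation (adjusted p = 0.0711). The 7mer-m8 class did so with DESeq2 (median -0.0587), an estimated correlation (adjusted p = 0.409), filterByExpr (-0.0520) and no filter (-0.0477), with medians from -0.0663 to -0.0517 as single libraries were left out. The miR-19 target list missed it with an estimated correlation (0.245) and at mean FPKM 5 (-0.133, where fewer members are tested). Gene lists called went from 15 to 3 with an estimated correlation, in a run that also used another gene statistic. fry, which asks whether the genes of a list move one way on balance, called 21. Among these were lists that camera did not call: glycolysis (fry adjusted p = 0.0022), p53 and YAP targets (both 0.0034) and TGF-beta response (0.0147). Heat shock (0.0211), S phase and autophagy genes (both 0.0350) were called by fry too. The mitochondrially encoded list was not called by fry (0.117). Among the site classes fry called the 8mer and 7mer-m8 classes downward (adjusted p = 0.00032 and 0.0170). It called the 6mer class (0.0036) and genes with no site (0.00016) upward, and did not call the 7mer-A1 class (0.0724). Families called went from 7 to 1 with DESeq2, filterByExpr, limma on TPM or no filter, to 0 with an estimated correlation or with genes carrying a miR-19a site kept, and lay between 1 (without miR-19a replicate 2 or miR-NC replicate 1) and 11 (without miR-19a replicate 3), with 4 without miR-19a replicate 1 and 2 without miR-NC replicate 3. Except for the smaller number of members, the cause was not tested. In the simulated counts the smallest fold was missed most often, with 34 of 50 genes recovered.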

Other observations

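The tests of miR-29 sites in matrix genes, of UTR length and GC content, of other endogenous microRNAs and of coding sites were chosen only after the result was seen, and the others were written before the result they measure.

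Further members of the marker lists moved strongly. Of the mesenchymal list, SPARC, a collagen-binding matrix protein, rose by 1.55 and the gelatinase MMP9 by 1.26, while the transcription factor TWIST1 fell by 0.79. Of the fibroblast list FBN1, fibrillin, rose by 0.48. These genes were named after their values were seen.

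NF-kB targets rose in the miR-19a samples (median 0.27). An innate response to the transfected RNA would raise interferon response genes as well, and their median was -0.014, with 10 members lower and 5 higher, which argues against it; both groups had received a transfected RNA. A lower level of an NF-kB inhibitor with a miR-19a site may contribute: CYLD, a deubiquitinase that restrains NF-kB, has an 8mer at 50797954 to 50797961 on chromosome 16 and fell by 0.2166 on the log2 scale (adjusted p = 0.016). TNFAIP3 also has an 8mer and did not pass at 0.10. Of all 631 genes with an 8mer 306 were lower, so a fall of a gene with such a site is common in these data. Whether so small a fall as that of CYLD raises these targets was not tested. Only CYLD and TNFAIP3 were named for this test, and other regulators of NF-kB were not examined.

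Of the 5 fibroblast markers above the filter 3 rose, and the call for the list did not hold with an estimated correlation (adjusted p = 0.245) or on the FPKM scale. Reads from lung fibroblasts would bring the abundant DCN, LUM, COL1A2 and COL3A1 along with COL1A1, and the summed rise of these 4 was 0.0334 (SE 0.0098) of the 16.7 CPM rise of COL1A1, which argues against it. Loss of repression through miR-29 sites stays open: these 3 (COL1A1, COL5A1 and FBN1) all carry TGGTGCT, against 14.2% of other tested genes (two-sided Fisher's exact test, p = 0.0028), but so do 5 of the 10 markers under the filter, so such sites are frequent in the list beyond these 3. The 2 tested markers that did not rise, TWIST2 and ACTA2, have none and are too few for a test (exact p = 0.1, the smallest that 3 against 2 genes can give). Direct or indirect effects of miR-19a stay open too.

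Genes with miR-29 sites stood higher with the preset correlation (adjusted p = 0.0054), but were not called with an estimated one (adjusted p = 0.224) or with genes carrying a miR-19a site kept (median 0.0786, adjusted p = 0.123). UTR length and GC content as the whole cause are argued against by TGGTGCT, which still had the highest statistic of all 7-mers after their smooth trend was removed (6.9953). Shuffled values, up to 3.53, are no measure of what such a trend leaves behind. GTGAACG (3.76) and TTTATGC (3.71), which match no family examined, passed them too. A part of the collagen genes in it stays open: the difference of medians was 0.0982 without them (990 genes with a site) and 0.0992 with them (1003 genes), but leaving out as many of the highest genes still gave 0.0971, so this test could not have shown it. Of 9 other families named for this test, 4 (let-7, miR-21, miR-27 and miR-30) lay above matched gene sets, in draws that treat genes as independent. Displacement of endogenous microRNAs from Argonaute by the transfected one stays open. Both groups had received a transfected RNA at the same concentration, so displacement common to both would cancel in this comparison. It could give this pattern only if it were stronger in the miR-19a samples than in the controls, which was not tested. Argonaute loading was not measured, and a change in the endogenous microRNAs themselves stays open.

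Most lower genes have no miR-19a site in the 3′ UTR. A part of sites in the coding sequence stays open, since the medians did not follow the strength of the site. No coding class passed after an adjustment that counted the genes with no coding site (n = 5880) as a further class. The coding 8mer class lay close to the threshold, and its call depends on whether that further class is counted. Among genes with no 3′ UTR site, those with a coding 8mer (n = 243) had a median of -0.03 against 0.03 for the others (limma's camera, p = 0.0118, adjusted p = 0.0591), those with a coding 7mer-A1 (n = 411) one of -0.04 (adjusted p = 0.0713), those with a coding 7mer-m8 (n = 361) one of -0.01 (adjusted p = 0.467, 97 higher and 88 lower), and those with a coding 6mer (n = 612) one of 0.01 (adjusted p = 0.467). Other routes were not tested.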
